A study of Mus musculus with 8 samples.

How the data were processed

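RNA of spleen cells from 8 male mice was hybridised to Affymetrix mouse arrays, 1 array per mouse. The labels give the age (2 or 12 months), the genotype (HMGA1a transgenic, TG, or wild type, WT) and a replicate number (1 or 2), which together define 4 groups of 2 mice. All 8 arrays were used. The deposited values are probe set intensities on a linear scale. Per the submitters' processing notes they were made with GCOS 1.4 and MAS5, which scales each array by 1 factor. In the values, the trimmed mean of every array (without the lowest and highest 0.02 of its values) was 150.001, and no log, floor or correction between groups was visible. The series' design text names a parametric and a nonparametric analysis by the authors, whose results were not used here.

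The table held 45101 probe sets, of which 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none in the probe annotation given. Symbols were brought to current names through gene identifiers for 34754 of the 34958 probe sets listed with 1 symbol. Values were taken as log2(signal + 16). Probe sets with a mean log2 value under the median of all probe sets were dropped, which left 22519, the dimmest with a mean signal of 45.3 on the log2 scale. Of these, 19307 had 1 symbol, and the probe set with the highest mean over all arrays stood for each gene, which gave 11189 genes. Some probe sets of this array type can bind transcripts of related genes, those of immunoglobulin segments and gene families in particular, so their values can mix several transcripts. Among probe sets with 1 symbol in the annotation given, none was named Hmga1, and probe sets with several symbols stood for no gene. The level of the transgene or of its mouse counterpart was therefore not analysed here. Xist was low and Y-linked genes were present on all 8 arrays, in keeping with male mice.

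The model had 4 group means and was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 4 residual degrees of freedom. It had no block. P-values are 2-sided and adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. Each group holds a mouse of either replicate number, so without a block the p-values measure the spread between mice together with the replicate difference, with n = 2. In every comparison fewer genes had an unadjusted p under 0.05 without the replicate number as a block than with it. The 5 comparisons were TG with WT at 2 months, TG with WT at 12 months, the difference of these 2 effects, and 12 with 2 months within WT and within TG. The effects of the transgene at the 2 ages share no array, and neither do the effects of age in the 2 genotypes. The effects at the 2 ages were also correlated across genes, without a p-value, since genes are not independent replicates.

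Before the data were examined, 27 gene lists were fixed, 14 of cell types (B cell, plasma cell, T cell, regulatory and exhausted T cell, lymphoid progenitor, NK and cytotoxic cell, macrophage and monocyte, neutrophil, erythroid, megakaryocyte and platelet, dendritic cell, mast cell and basophil, stroma and endothelium, exocrine pancreas) and 13 of processes (G2/M and mitosis, DNA replication, D-type cyclins and CDK inhibitors, growth and ribosome production under MYC, inflammatory cytokines and NF-kB, interferon response, pluripotent stem cell, hematopoietic stem and progenitor, glycolysis and hypoxia, p53 targets, immediate early genes, MHC class II presentation, HMG proteins). Their themes were chosen knowing the themes of the study and their members from general knowledge. Lists with at least 5 measured genes were tested with limma camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison. Camera compares a list with the other genes. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance 1 way, were run beside it. Where the text gives "adjusted over the list alone", the gene p-values were adjusted within the list.

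The genes named were chosen by a rule also fixed before the data were examined. For each comparison of TG with WT it takes up to 12 genes per direction among those past the test whose 2 TG arrays lie on 1 side of the 2 WT arrays, and where none passed, the 6 with the smallest p in each direction. For the other comparisons it takes 6, or 3 where none passed. From each shifted list it takes up to 4 members with the largest moderated t, of which the text names the first 3 at 12 months and the first 2 elsewhere. Immunoglobulin and T cell receptor segments, clone names and predicted genes are counted but not named among top genes. Genes past the test with the replicate block were added after the data were examined.

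The replicate number was checked as a possible batch. Differences between replicate 1 and replicate 2 correlated across genes between all 6 pairs of groups, with r from 0.464 to 0.654, so the number marks a batch. Arrays correlated at 0.951 to 0.984 within a replicate number and at 0.935 to 0.957 within a group. The first principal component held 41.3% of the variance and parted the replicate numbers, the second held 22.6% and parted the TG arrays of 12 months from the others. The signal of the 18S ribosomal control was 121 ± 36.5 on the 4 replicate 1 arrays and 967 ± 141 on the 4 replicate 2 arrays, and the spiked control BioC was 2.13 times as high on the latter, while BioB was 1.05 times as high. With the replicate number as a block, 2940 genes differed between the replicate numbers (limma adjusted p under 0.05). Since each group has 1 mouse of each number, medians of lists within replicate 1 and within replicate 2 are printed beside the pooled ones in the report, and the blocked test, with 3 residual degrees of freedom, is given where it changes a call or a count. Ratios of the 3' to the 5' control probe set were 0.843 to 1.73 for Gapdh and 1.10 to 1.48 for beta-actin, and at 12 months both were lower in TG than in WT mice within replicate 1 and within replicate 2.

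The fit was tested on simulated data with the spread of the 12-month comparison. In 5 runs with 200 changed genes it recovered 11.8% of changes of log2 1 and 71.4% of changes of log2 2 with 0.4 false calls on average, and with the block 56.6%, 90.0% and 5.6. All simulated lists of 20 genes shifted by 0.5 were called, and 3.4% of unshifted lists had a p under 0.05. The simulated genes varied independently of each other, so these rates do not cover lists whose genes move together. The spread was the same in all groups, so they do not cover a group whose mice differ more than the others. The alternatives tried were quantile, cyclic loess and median scaling of the arrays, no filter and a stricter filter on dim probe sets, a pseudocount of 1 or 64, eBayes without the trend or robust, an unmoderated linear model, a fit to the arrays of the comparison alone, the mean of a gene's probe sets or every probe set by itself, the replicate block, an adjusted p under 0.1 or an absolute log2 fold change of at least 1, both other list tests, and leaving out each array in turn. In the last, genes stayed those of the full fit and the lone mouse left in a group is assumed to vary like the other groups. These fits have no block unless one is named. Leaving out an array of a comparison then unbalances the replicate numbers, so a change can hold the replicate difference as well as the mouse. With groups of 2 mice, regrouping the samples was not used as a test.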

Results

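Gene expression was measured in spleen cells of 8 male C57/BL6 mice on Affymetrix whole-genome mouse arrays, with 1 array per mouse. The mice either carried a transgene for HMGA1a, an architectural chromatin protein that binds AT-rich DNA (TG), or were control littermates without it (WT). Each genotype was sampled at 2 months and at 12 months of age, with 2 mice in each of the 4 groups. By the series' design text, every TG mouse develops lymphoid tumours, and the younger age lies ahead of tumour onset and the older age follows it. Values are probe set signals on a linear scale, given as mean ± SD with n = 2, and log2 fold changes are given ± SE. The median signal of an array lay between 44.9 and 49.5, and 25% to 28.7% of the probe sets of an array had a signal under 16. With 2 mice per group, the number of arrays limits the precision of every value.

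TG mice were first set against WT mice at 12 months, the age of overt disease. Genes for ribosome production and growth, for DNA replication and for mitosis were higher in the TG spleens, whereas markers of dendritic cells, mature B cells and macrophages were lower (limma camera at a preset correlation). None of these 6 calls held with an estimated correlation (adjusted p = 0.257 to 0.458), and the B cell and macrophage calls were lost without the replicate 1 TG mouse of 12 months. The ratio of the 3' to the 5' control probe set, a sign of RNA quality, moved with these 6 lists: it was lower in TG than in WT mice within both replicates, at 0.843 against 1.25 and 1.21 against 1.73 for Gapdh, and 1.20 against 1.48 and 1.10 against 1.31 for beta-actin. Expression of Lgals1, which encodes the sugar-binding protein galectin-1, was 3275 ± 700 in TG and 1018 ± 301 in WT mice, and that of Gzmm, the cytotoxic granule protease granzyme M, was 759 ± 466 and 82.5 ± 1.99. In the other direction, Gzma, which encodes granzyme A, had a signal of 66.0 ± 33.3 in TG and 338 ± 0.732 in WT mice. The complement receptor gene Cr2 had 495 ± 98.5 and 1480 ± 180, and Fcer2a, the low-affinity IgE receptor of B cells, had 382 ± 119 and 1117 ± 442.

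None of 11189 genes passed the test at 12 months (limma, smallest adjusted p = 0.232), although 865 had an unadjusted p under 0.05, 290 higher and 575 lower in TG mice (2227 with the replicate block). Chance gives 559 in a test whose error holds no batch, so this baseline is too high for the fit without a block. There the replicate difference, which cancels from the comparison, widens the error. The same holds for each comparison below. As no gene passed, the genes with the smallest p in each direction missed the test. Those higher in TG mice were Gzmm (log2 fold change 2.83 ± 0.37), the phospholipid scramblase gene Plscr1 (1.20 ± 0.19), the spindle protein gene Psrc1 (1.74 ± 0.31), Lgals1 (1.68 ± 0.30), the macrophage complement receptor gene Vsig4 (1.65 ± 0.31) and the coenzyme Q biosynthesis gene Coq4 (1.48 ± 0.29). Those lower in TG mice were Gzma (-2.17 ± 0.27), Cr2 (-1.56 ± 0.20), the prostacyclin synthase gene Ptgis (-1.81 ± 0.30), Brwd1 (-1.17 ± 0.20), Igfbp5 (-1.57 ± 0.27) and the phosphatase gene Ptpro (-1.27 ± 0.22). Within replicate 1 and replicate 2 the differences were 3.47 and 2.20 for Gzmm and -2.60 and -1.74 for Gzma. With the replicate number as a block, 5 genes passed the test: Lgals1 was higher in TG mice (adjusted p = 0.00286), and Cr2 (0.0255), Fcer2a (0.0255), the immunoglobulin segment Ighv14-2 (0.0255) and Gzma (0.0381) were lower. That count hung on single arrays. It was 731 without the replicate 2 TG mouse of 12 months, 47 without the replicate 1 TG mouse, 0 without either WT mouse of 12 months and 1 without either WT mouse of 2 months. Without a block, 7 genes passed once the replicate 2 TG mouse was left out.

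**Figure D1:**
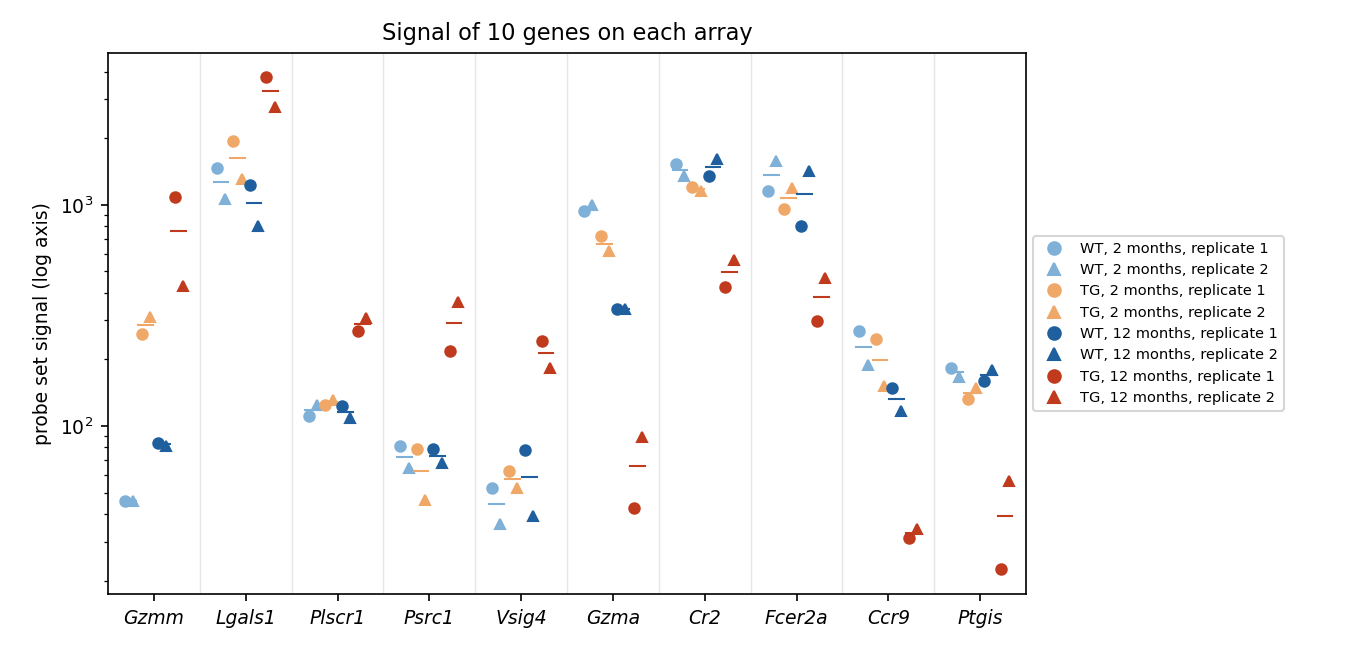
Signal of 10 genes (log axis) on each of the 8 arrays, coloured by group, with circles for replicate 1, triangles for replicate 2 and a line at the mean of each group. At 12 months both TG arrays lie above both WT arrays for Gzmm, Lgals1, Plscr1, Psrc1 and Vsig4, and below them for Gzma, Cr2, Fcer2a, Ccr9 and Ptgis.

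Of the 26 gene lists tested at 12 months, 13 were shifted (limma camera), 8 up and 5 down, all beside the lower control ratios of the TG arrays given above. The 22 genes of growth and ribosome production under the transcription factor MYC rose, with all 22 higher in TG mice and a median log2 fold change of 0.46 (0.46 within replicate 1 and 0.37 within replicate 2, camera adjusted p = 3.19e-10, and adjusted p = 0.257 with an estimated correlation). They included the RNA polymerase I subunit Polr1b (243 ± 9.02 in TG and 122 ± 16 in WT mice), the cap-binding translation factor Eif4e (1013 ± 134 and 583 ± 38.8) and the nucleolar protein Nolc1 (524 ± 49.0 and 353 ± 19.2). The median of this list was 0.31 without the replicate 1 WT mouse of 12 months. DNA replication genes rose as well, with 29 of 30 higher and a median of 0.46 (0.51 and 0.26 within the replicates, adjusted p = 3.19e-10, and adjusted p = 0.449 with an estimated correlation). Examples were the clamp loader subunits Rfc5 (425 ± 21.9 and 240 ± 7.21) and Rfc4 (228 ± 87.7 and 124 ± 31.1) and the replication initiator Mcm10 (213 ± 19.0 and 122 ± 13.6). All 25 genes of G2/M and mitosis were higher, with a median of 0.53 (0.52 and 0.52 within the replicates, adjusted p = 4.09e-10, and adjusted p = 0.449 with an estimated correlation). Examples were the mitotic kinesin Kif20a (159 ± 17.9 and 78.0 ± 21.2), the spindle checkpoint kinase Bub1b (411 ± 25.6 and 228 ± 22.5) and Nusap1 (853 ± 79.0 and 496 ± 79.7). Both TG signals lay above both WT signals for 16 of the 22 growth genes, 21 of the 30 replication genes and 21 of the 25 mitosis genes. Chance gives 16.7% for a single gene, and 14.3% of all genes tested lay so. Genes of a list can move together, so these counts are not of independent genes. Adjusted over the list alone, 2 growth genes passed the test (16 with the replicate block), and 0 replication genes (5 with the block) and 0 mitosis genes did. These 3 lists moved beside markers of blood cell precursors only in part: the erythroid list had a median of -0.19 within replicate 1 and 0.34 within replicate 2, and the neutrophil list -0.10 and 1.69.

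**Figure D2:**
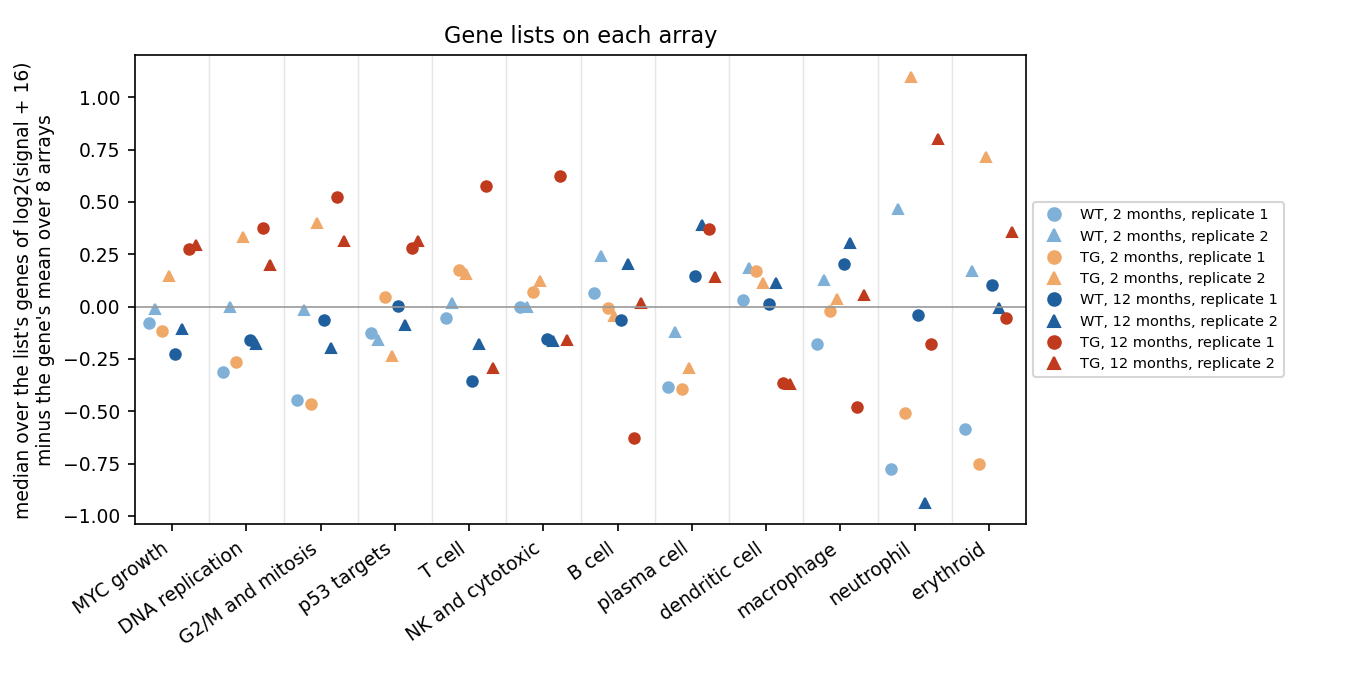
Gene lists on each of the 8 arrays. The vertical axis is the median over a list's genes of log2(signal + 16) minus the gene's mean over all arrays, and symbols are as in the plot of gene signals. The growth list stands at 0.28 and 0.29 on the TG arrays of 12 months and at no more than 0.14 on the other 6, and the dendritic cell list at -0.37 and -0.37 against at least 0.01.

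Among immune cell markers at 12 months, the dendritic cell list fell in the TG spleens, with 10 of 12 genes lower and a median of -0.49 (-0.44 and -0.44 within the replicates, adjusted p = 9.2e-05, and adjusted p = 0.257 with an estimated correlation). It was the 1 list that also passed fry at this age (adjusted p = 0.0306). Its members included the transcription factor Irf8 (1772 ± 42.7 in TG and 2691 ± 62.1 in WT mice), the migration receptor Ccr7 (399 ± 17.8 and 585 ± 63.3) and the lectin Cd209a (61.3 ± 13.0 and 118 ± 0.229). B cell genes fell, with 16 of 19 lower and a median of -0.36 (-0.57 and -0.30, adjusted p = 4.83e-05, and adjusted p = 0.449 with an estimated correlation). Cr2, Fcer2a and Siglecg (643 ± 343 and 1239 ± 281) led them. Macrophage and monocyte genes fell, with 17 of 22 lower and a median of -0.49 (-0.75 and -0.15, adjusted p = 8.17e-05, and adjusted p = 0.458 with an estimated correlation). Among them were the endotoxin co-receptor Cd14 (282 ± 142 and 716 ± 30.6), Vcam1 (3246 ± 570 and 5299 ± 558) and the mannose receptor Mrc1 (780 ± 328 and 1429 ± 257). The lymphoid progenitor list fell with a median of -0.37 (8 of 10 genes lower, -0.48 and -0.31, adjusted p = 0.0122, and adjusted p = 0.418 with an estimated correlation). It held the gut-homing receptor Ccr9 (32.7 ± 2.38 and 132 ± 21.8), Flt3 (178 ± 1.20 and 256 ± 2.34) and Kit (210 ± 5.16 and 281 ± 16). MHC class II presentation fell with a median of -0.25 (8 of 9 genes lower, -0.10 and -0.40, adjusted p = 0.039, and adjusted p = 0.458 with an estimated correlation). Among them were H2-Ob (962 ± 13.2 and 1882 ± 159), H2-Oa (897 ± 150 and 1190 ± 175) and H2-Ab1 (5277 ± 433 and 6410 ± 622). Leaving out the replicate 1 TG mouse of 12 months ended the calls of the B cell (-0.15), macrophage (-0.16), lymphoid progenitor (-0.32) and class II (-0.16) lists. Without the replicate 2 TG mouse the B cell median was -0.82 and the class II median -0.47, which missed the test, and without the WT mice of 12 months the class II median was -0.46 (replicate 1) and -0.01 (replicate 2, test missed).

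T cell genes were higher in TG mice at 12 months with a median of 0.52, but the shift was 0.96 within replicate 1 and -0.12 within replicate 2 (16 of 21 genes higher, adjusted p = 4.83e-05, and adjusted p = 0.449 with an estimated correlation). Signals were 827 ± 498 in TG and 297 ± 47.5 in WT mice for the CD8 chain Cd8b1. They were 903 ± 21.8 and 550 ± 54.1 for Cd2, and 385 ± 87.4 and 236 ± 3.87 for the kinase Zap70. Neutrophil genes showed the reverse split, with a median of 0.86 made of -0.10 within replicate 1 and 1.69 within replicate 2 (13 of 16 genes higher, adjusted p = 0.00243, and adjusted p = 0.622 with an estimated correlation). Elane had 332 ± 111 in TG and 169 ± 129 in WT mice, Fcnb 136 ± 80.5 and 60.2 ± 6.53, and Cxcr2, which went the other way, 18.2 ± 10.4 and 39.1 ± 7.92. Targets of p53 rose with a median of 0.11 (7 of 12 genes higher, 0.17 and 0.32, adjusted p = 0.00999, and adjusted p = 0.379 with an estimated correlation). Among them were the cell cycle inhibitor Cdkn1a (291 ± 68.4 and 169 ± 27.5), Ccng1 (1325 ± 224 and 764 ± 242) and Zmat3 (235 ± 37.1 and 143 ± 3.53). Glycolysis and hypoxia genes rose with a median of 0.24 (10 of 14 genes higher, 0.38 and 0.03, adjusted p = 0.00999, and adjusted p = 0.449 with an estimated correlation). Pgam1 stood at 932 ± 224 and 574 ± 62.1, Tpi1 at 926 ± 236 and 635 ± 85.3, and Pfkp at 675 ± 230 and 444 ± 76.3. The interferon list had a median of 0.15 (12 of 18 genes higher, 0.31 and -0.07, adjusted p = 0.0347, and adjusted p = 0.491 with an estimated correlation), a call that the replicate block ended (adjusted p = 0.093). Zbp1 had 282 ± 91.1 and 158 ± 28.6, Psmb8 3124 ± 326 and 2222 ± 669, and Gbp2 781 ± 284 and 508 ± 154.

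Several of these values changed when 1 array was left out, in fits without a block. Without the replicate 1 TG mouse of 12 months the median of the T cell list was -0.01, that of the interferon list -0.07, that of glycolysis 0.05 and that of the p53 targets 0.35, all 4 then missing the test. That of the neutrophil list was 1.32. Without the replicate 2 TG mouse the medians were 0.88 for T cells, 0.33 for interferon, 0.48 for glycolysis, 0.32 for p53 targets and 0.30 for neutrophils, the last of which missed the test. Without the replicate 1 WT mouse they were 0.33 for T cells, 0.01 for interferon (test missed) and 0.47 for p53 targets, and without the replicate 2 WT mouse 0.23 for p53 targets and 0.36 for neutrophils, both missing the test. Other settings also ended calls: the stricter filter on dim probe sets that of p53 targets (adjusted p = 0.101), the mean of a gene's probe sets that of lymphoid progenitors (median -0.24, adjusted p = 0.0918), and the unmoderated model that of MHC class II (0.0674). The interferon call was lost with no filter (0.056), with the unmoderated model (0.106) and with the mean of a gene's probe sets (0.108). With that mean the p53 median was 0.30, and with loess scaling the class II median was -0.39. The number of shifted lists was 5 without the replicate 1 TG mouse. With an estimated correlation none of the 13 passed.

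The other 13 lists were not shifted at 12 months. Medians, with those within replicate 1 and replicate 2 and the camera adjusted p in brackets, were 0.28 for NK and cytotoxic cells (0.66 and -0.03, adjusted p = 0.0762), 0.18 for D-type cyclins and CDK inhibitors (0.14 and 0.21, 0.0613), -0.33 for immediate early genes (-0.22 and -0.27, 0.0749) and 0.21 for regulatory and exhausted T cells (0.58 and -0.28, 0.274). They were -0.24 for megakaryocytes and platelets (-0.63 and 0.12, 0.264), 0.07 for erythroid cells (-0.19 and 0.34, 0.405), 0.09 for plasma cells (0.25 and -0.15, 0.411), 0.38 for exocrine pancreas (0.78 and -0.04, 0.411) and 0.09 for HMG proteins (0.43 and -0.17, 0.411). The last 3 were 0.02 for stroma and endothelium (0.03 and 0.06, 0.615), -0.09 for hematopoietic stem and progenitor cells (-0.22 and 0.09, 0.615) and -0.11 for inflammatory cytokines and NF-kB (0.16 and -0.16, 0.994). The pluripotent stem cell list, of which 5 genes were measured, had a median of 0.17 (-0.20 and -0.05 within the replicates), a mean of -0.16 and a test direction of down (0.411). The mast cell and basophil list had 2 measured genes and was not tested.

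The same contrast at 2 months asked what the transgene changes ahead of tumours. Gzmm, which had the smallest p among genes higher in TG mice at 12 months, had the smallest p of all genes here, at 286 ± 36.5 in TG and 45.9 ± 0.184 in WT mice (log2 fold change 2.28 ± 0.37, 2.16 within replicate 1 and 2.40 within replicate 2). No gene passed the test (limma, smallest adjusted p = 1.00), and 44 had an unadjusted p under 0.05, 33 higher and 11 lower (189 with the replicate block), where chance gives 559. Behind Gzmm came Tmem181a (1.42 ± 0.32), the muscle protein gene Myoz1 (1.07 ± 0.33), Eps8l1 (1.34 ± 0.41), Tmc8 (0.71 ± 0.24) and Omp (0.68 ± 0.22) among genes higher in TG mice. Among lower ones came Upk2 (-0.54 ± 0.20), H2-M10.1 (-0.87 ± 0.33), Mrpl48 (-0.51 ± 0.20), Cdk5rap1 (-0.79 ± 0.32), the lipid kinase gene Pikfyve (-0.46 ± 0.18) and Txndc16 (-0.44 ± 0.18). All 12 missed the test. Without the replicate 2 WT mouse of 2 months, the lipase gene Cel and 2210010C04Rik had log2 fold changes of -4.32 and -4.86. The WT side was then the replicate 1 array alone, the only array with a high signal of exocrine pancreas genes.

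Of 26 lists, 6 were shifted at 2 months, 4 up and 2 down. B cell genes fell, with 18 of 19 lower in TG mice and a median of -0.20 (-0.12 and -0.28 within the replicates, camera adjusted p = 4.25e-06, and adjusted p = 0.846 with an estimated correlation). Among them were Vpreb3 (328 ± 38.4 in TG and 415 ± 39.8 in WT mice) and Cd72 (956 ± 92.8 and 1189 ± 126). The B cell median was -0.11 without the replicate 2 WT mouse of 2 months. The other 5 calls were lost or turned when 1 array was left out, in fits without a block. Of these lists only that of the exocrine pancreas differed in sign between the replicates, and the other 4 had higher medians in TG mice within both. Exocrine pancreas genes had a median of -1.84, made of -3.69 within replicate 1 and 0.11 within replicate 2 (8 of 8 genes lower, adjusted p = 7.15e-10, and adjusted p = 0.846 with an estimated correlation). The replicate 1 WT mouse of 2 months alone carried a high signal of these genes, as for the elastase Cela1 (378 ± 7.61 in TG and 1979 ± 2323 in WT mice) and the chymotrypsinogen Ctrb1 (54.3 ± 58.7 and 1069 ± 1453). Without that mouse the pancreas median was 0.35, and camera then called the list higher in TG mice. Without the replicate 2 WT mouse the pancreas median was -4.21. The G2/M list had a median of 0.23 (25 of 25 genes higher, 0.02 and 0.47, adjusted p = 0.00013, and adjusted p = 0.912 with an estimated correlation). Tpx2 stood at 247 ± 134 and 169 ± 49.3, and Nusap1 at 628 ± 300 and 460 ± 73.5. DNA replication genes had a median of 0.14 (28 of 30 genes higher, 0.03 and 0.30, adjusted p = 0.000343, and adjusted p = 0.912 with an estimated correlation). Fen1 stood at 1267 ± 419 and 859 ± 208, and Ccne1 at 420 ± 211 and 288 ± 44.6. Neutrophil genes had a median of 0.44 (14 of 16 genes higher, 0.23 and 0.71, adjusted p = 0.0162, and adjusted p = 0.92 with an estimated correlation). Ctsg stood at 111 ± 86.5 and 34.8 ± 25.6, and Cxcr2 at 80.8 ± 2.42 and 124 ± 49.8. T cell genes had a median of 0.19 (17 of 21 genes higher, 0.31 and 0.11, adjusted p = 0.0282, and adjusted p = 0.917 with an estimated correlation), a call that the replicate block ended (adjusted p = 0.0543). Cd8b1 stood at 649 ± 60.1 and 451 ± 16.6, and Trat1, which went the other way, at 45.4 ± 14.2 and 75.5 ± 3.61.

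Without the replicate 2 TG mouse of 2 months the medians of G2/M, DNA replication and neutrophil genes at 2 months turned to -0.15, -0.10 and -0.46. Camera then called all 3 lists lower in TG mice. That fit has no block and sets a replicate 1 TG array against WT arrays of both replicate numbers, so the replicate difference enters it. Within replicate 1 none of these lists had a lower median in TG mice. Without the replicate 1 WT mouse the 3 medians were 0.06, 0.03 and -0.18, all 3 missing the test. They were 0.67, 0.48 and 1.19 without the replicate 1 TG mouse, and 0.43, 0.33 and 1.06 without the replicate 2 WT mouse. The T cell call at this age was lost without the replicate 1 WT mouse (0.16), the replicate 2 WT mouse (0.22) or the replicate 1 TG mouse (0.18). The T cell and neutrophil calls were also lost with no filter on dim probe sets (adjusted p = 0.111 and 0.0815) and with the unmoderated model (0.206 and 0.248). With the replicate block the MYC growth list, with a median of 0.10 (0.01 and 0.20 within the replicates), was shifted up as well (adjusted p = 0.0411, and 0.112 without the block). The number of shifted lists was 3 without the replicate 1 WT mouse and 10 without the replicate 1 TG mouse. None of these lists passed with an estimated correlation or with fry.

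**Figure D3:**
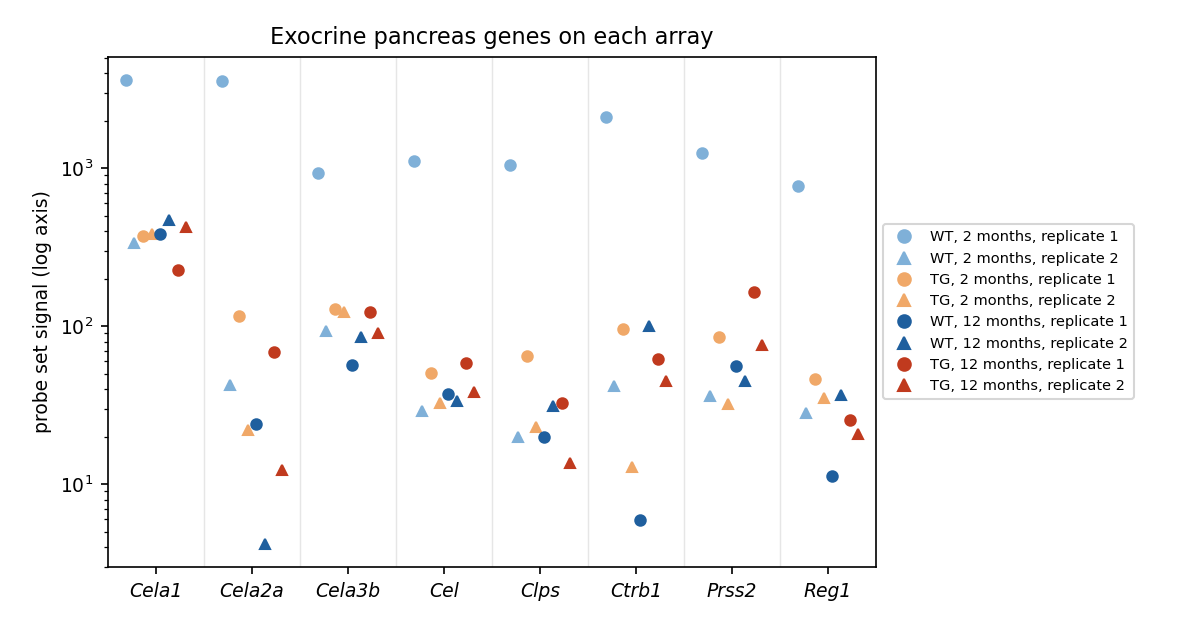
Signal of the exocrine pancreas genes that passed the filter (log axis) on each of the 8 arrays, with symbols as in the plot of gene signals. Over the 19 probe sets of this list the median signal was 1503 on the array of the replicate 1 WT mouse of 2 months and between 13.7 and 82.4 on the other 7 arrays.

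Whether the transgene's effect grew between 2 and 12 months was tested as the difference of the 2 effects. The MYC growth list gained most clearly, with a median difference of 0.35 (19 of 22 genes up, 0.44 within replicate 1 and 0.17 within replicate 2, camera adjusted p = 2.47e-07, and adjusted p = 0.315 with an estimated correlation), as for Eif4e (0.69 ± 0.26) and Polr1b (0.75 ± 0.30). The dendritic cell list moved the other way, by -0.47 (10 of 12 genes down, -0.49 and -0.39, adjusted p = 0.000208, and adjusted p = 0.315 with an estimated correlation), as for Flt3 (-0.78 ± 0.25) and Irf8 (-0.54 ± 0.24). No array left out changed either call. No single gene passed (limma, smallest adjusted p = 1.00), and 213 had an unadjusted p under 0.05, 58 up and 155 down, where chance gives 559. With the replicate block 911 did, above chance, and again none passed (smallest adjusted p = 0.218). The smallest p values belonged to Psrc1 (1.94 ± 0.43), Plscr1 (1.10 ± 0.27) and the ubiquitin-conjugating enzyme gene Ube2d3 (0.83 ± 0.25) upward. Downward they belonged to Tmem181a (-2.20 ± 0.45), Cr2 (-1.29 ± 0.28) and Gzma (-1.64 ± 0.38). All 6 missed the test.

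In all, 9 lists differed between the ages, 7 up and 2 down. The other 7 each lost the call when 1 array was left out, in fits without a block. At 2 months the Gapdh control ratio was higher in TG than in WT mice within both replicates (1.07 against 1.01 and 1.48 against 1.39), and that of beta-actin was lower (1.21 against 1.24 and 1.14 against 1.18). The macrophage list had a median difference of -0.50 (18 of 22 genes down, -1.01 and -0.08, adjusted p = 3.41e-05, and adjusted p = 0.63 with an estimated correlation). Cd14 stood at -1.55 ± 0.47, and Mrc1 at -0.93 ± 0.40. The macrophage list missed the test without the replicate 1 TG mouse of 12 months (-0.19). DNA replication differed by 0.24 (27 of 30 genes up, 0.53 and -0.02, adjusted p = 3.41e-05, and adjusted p = 0.634 with an estimated correlation). Rfc5 stood at 0.73 ± 0.27, and Rfc4 at 0.71 ± 0.39. G2/M differed by 0.31 (24 of 25 genes up, 0.57 and 0.07, adjusted p = 8.28e-05, and adjusted p = 0.634 with an estimated correlation). Kif20a stood at 0.66 ± 0.41, and Bub1 at 0.82 ± 0.52. These 2 lists turned to -0.08 and -0.11 without the replicate 1 TG mouse of 2 months and were 0.21 and 0.25 without the replicate 1 TG mouse of 12 months, missing the test each time. Without the replicate 1 or replicate 2 WT mouse of 2 months they were 0.42 and 0.55, or 0.14 and 0.13 (G2/M then missing the test), and without the replicate 2 TG mouse of 2 months 0.54 and 0.77. DNA replication alone also moved to 0.38 without the replicate 1 WT mouse and 0.36 without the replicate 2 TG mouse of 12 months. The T cell list differed by 0.34 (16 of 21 genes up, 0.76 and -0.29, adjusted p = 0.00584, and adjusted p = 0.634 with an estimated correlation). Cd2 stood at 0.68 ± 0.31, and Cd8b1 at 0.80 ± 0.52. The T cell list had -0.17 without the replicate 1 TG mouse, 0.65 without the replicate 2 TG mouse and 0.15 without the replicate 1 WT mouse of 12 months, the first and last missing the test.

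The exocrine pancreas list differed between the ages by 2.04 (8 of 8 genes up, 4.43 and -0.14 within the replicates, adjusted p = 7.29e-05, and adjusted p = 0.63 with an estimated correlation). Prss2 stood at 2.84 ± 1.72, and Cela2a at 3.47 ± 2.30. That median was 0.05, with the test missed, without the replicate 1 WT mouse of 2 months and 4.38 without the replicate 2 WT mouse. Glycolysis genes differed by 0.25 (12 of 14 genes up, 0.45 and 0.09, adjusted p = 0.0164, and adjusted p = 0.63 with an estimated correlation). Pgam1 stood at 0.63 ± 0.33, and Tpi1 at 0.42 ± 0.31. Glycolysis genes turned to -0.02, with the test missed, without the replicate 1 TG mouse of 12 months, had 0.49 without the replicate 2 TG mouse, 0.11 without the replicate 2 WT mouse of 12 months and 0.14 without that of 2 months. They missed the test at 0.19 without the replicate 1 WT mouse and at 0.16 without the replicate 2 TG mouse of 2 months. Targets of p53 differed by 0.12 (9 of 12 genes up, 0.01 and 0.21, adjusted p = 0.00674, and adjusted p = 0.315 with an estimated correlation). Ccng1 stood at 0.85 ± 0.36, and Cdkn1a at 0.83 ± 0.38. The p53 list missed the test without the replicate 2 TG mouse of 2 months (0.13), the replicate 2 WT mouse of 12 months (0.15) or the replicate 1 TG mouse of 12 months (0.34), and lay between 0.21 and 0.50 without each of the other arrays. It also missed the test with the stricter filter on dim probe sets (adjusted p = 0.112), and its median was 0.30 with the mean of a gene's probe sets. With the replicate block the megakaryocyte and platelet list, with a median of -0.34 (-0.70 and 0.02 within the replicates), differed as well (adjusted p = 0.0422, and 0.0671 without the block). The number of lists that differed was 4 without the replicate 1 TG mouse of 12 months, 16 without the replicate 2 TG mouse and 14 without the replicate 2 TG mouse of 2 months. Across the 11189 genes, which are not independent replicates, the effects at the 2 ages had a Pearson r of 0.212 and a Spearman rho of 0.206, and 57.4% of the genes had the same sign. Within replicate 1 the r was 0.0538 and within replicate 2 it was 0.176. It was 0.0696 without the replicate 2 TG mouse of 2 months and 0.123 without the replicate 2 TG mouse of 12 months. Of the genes with an unadjusted p under 0.05 at both ages, 4 were higher in TG mice at both (Gzmm, Shmt1, Gm5124 and Cacnb1), where independent lists give 0.855. Apart from Gzmm these genes were picked out after their values were seen. None was lower at both (0, where independent lists give 0.565). Both p-values of a gene rest on the same estimate of its spread, so the lists of the 2 ages are not independent and these baselines are only rough.

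Age was compared within WT mice, which gives the change without disease. Plasma cell genes rose between 2 and 12 months in the WT spleens, with all 14 higher and a median of 0.46 (0.52 and 0.48 within the replicates, camera adjusted p = 2.58e-13, and adjusted p = 0.489 with an estimated correlation). The surface proteoglycan Sdc1 had 361 ± 46.7 at 12 and 178 ± 38.0 at 2 months, and Derl3, of the degradation pathway in the endoplasmic reticulum, had 383 ± 119 and 169 ± 46.5. Interferon response genes fell, with 16 of 18 lower and a median of -0.19 (-0.22 and -0.33, adjusted p = 9.62e-06, and adjusted p = 0.489 with an estimated correlation). Among them were Oasl2 (124 ± 3.14 and 220 ± 64.9) and Oas1a (332 ± 25.1 and 472 ± 27.7). The interferon median was -0.24 without the replicate 1 WT mouse of 12 months, which ended the call, -0.35 without the replicate 2 WT mouse of 12 months and -0.33 without the replicate 1 WT mouse of 2 months. No gene passed (limma, smallest adjusted p = 1.00), and 171 had an unadjusted p under 0.05, 106 higher and 65 lower at 12 months, where chance gives 559 (578 with the replicate block, smallest adjusted p = 0.362). The smallest p values upward belonged to the complement gene C6 (1.04 ± 0.21), Sdc1 (0.97 ± 0.23) and Depp1 (2.12 ± 0.52). Downward were Gzma (-1.48 ± 0.27), D13Ertd608e (-0.90 ± 0.20) and the chemokine receptor gene Cxcr2 (-1.31 ± 0.33), and all 6 missed the test. Without the replicate 2 WT mouse of 2 months, Cela3b, Cel, Reg1 and 2210010C04Rik had log2 fold changes of -3.47, -4.46, -4.39 and -5.05. The younger side was then the array with the high pancreatic signal alone.

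A further 8 lists were shifted with age in WT mice, so that 10 of 26 were, 3 up and 7 down. The 3' to 5' control ratios were higher at 12 months in both replicates (Gapdh 1.25 against 1.01 and 1.73 against 1.39, beta-actin 1.48 against 1.24 and 1.31 against 1.18). T cell genes fell with a median of -0.28 (20 of 21 genes lower, -0.32 and -0.17, adjusted p = 0.000115, and adjusted p = 0.54 with an estimated correlation). Cd8b1 stood at 297 ± 47.5 at 12 and 451 ± 16.6 at 2 months, and Trat1 at 43.5 ± 16.8 and 75.5 ± 3.61. NK and cytotoxic genes fell with a median of -0.20 (11 of 17 genes lower, -0.26 and -0.16, adjusted p = 0.00273, and adjusted p = 0.523 with an estimated correlation). Gzma stood at 338 ± 0.732 and 969 ± 47.0, and Ncr1 at 51.9 ± 2.16 and 84.3 ± 7.20. Both calls were lost without the replicate 1 WT mouse of 12 months (-0.16 and -0.19), and the NK call with the stricter filter on dim probe sets (adjusted p = 0.11). Macrophage genes rose with a median of 0.24 (18 of 22 genes higher, 0.43 and 0.07, adjusted p = 0.000567, and adjusted p = 0.54 with an estimated correlation). Cd14 stood at 716 ± 30.6 and 288 ± 88.1, and Mrc1 at 1429 ± 257 and 937 ± 36.7. This median was 0.11 and missed the test without the replicate 1 WT mouse of 2 months, and was 0.38 without the replicate 2 mouse. The MYC growth list fell with a median of -0.09 (19 of 22 genes lower, -0.13 and -0.11, adjusted p = 0.00768, and adjusted p = 0.523 with an estimated correlation). Hspe1 stood at 1517 ± 304 and 1957 ± 24.7, and Rrp9 at 42.9 ± 6.27 and 70.3 ± 40.5. This call was lost without the replicate 1 (-0.12) or replicate 2 (-0.10) WT mouse of 2 months or the replicate 1 WT mouse of 12 months (-0.06), and the median was -0.17 without the replicate 2 WT mouse of 12 months.

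The remaining 4 age shifts in WT mice changed sign when 1 mouse was left out, each then missing the test. Neutrophil genes had a median of -0.40 (15 of 16 genes lower, 0.69 and -1.38, adjusted p = 0.00144, and adjusted p = 0.672 with an estimated correlation). Cxcr2 stood at 39.1 ± 7.92 and 124 ± 49.8, and Mmp8 at 48.7 ± 24.7 and 136 ± 124. The neutrophil list stood at 0.26 and 0.04 without the replicate 2 WT mouse of 2 or of 12 months and at -0.84 and -0.81 without the replicate 1 mouse of those ages. Erythroid genes had 0.27 (15 of 15 genes higher, 0.73 and -0.18, adjusted p = 0.0164, and adjusted p = 0.753 with an estimated correlation). Car1 stood at 806 ± 7.06 and 603 ± 17.8, and Rhag at 688 ± 295 and 487 ± 91.4. Erythroid genes stood at -0.10 without the replicate 1 WT mouse of 2 months, at 0.62 without the replicate 2 mouse of that age and at 0.22, with the test missed, without the replicate 1 WT mouse of 12 months. Stroma and endothelium genes had -0.19 (11 of 14 genes lower, -0.05 and -0.33, adjusted p = 0.00504, and adjusted p = 0.489 with an estimated correlation). The collagen gene Col3a1 stood at 1001 ± 172 and 1655 ± 72.0, and Col1a2 at 1076 ± 91.4 and 1605 ± 496. The stroma list stood at 0.01 without the replicate 2 WT mouse of 2 months and at -0.10, with the test missed, without the replicate 2 WT mouse of 12 months. The exocrine pancreas list had -2.20 (8 of 8 genes lower, -4.64 and 0.24, adjusted p = 3.29e-09, and adjusted p = 0.489 with an estimated correlation). Cela2a stood at 14.2 ± 14.1 and 1812 ± 2503, and Cela3b at 71.1 ± 20.7 and 516 ± 598. The pancreas list stood at 0.00 without the replicate 1 WT mouse of 2 months and at -4.43 without the replicate 2 mouse. The unmoderated model ended the erythroid and stroma calls (adjusted p = 0.157 and 0.079), and the stroma median was -0.07 with no filter on dim probe sets. The number of shifted lists was 6 without the replicate 1 WT mouse of 2 months and 5 without the replicate 1 WT mouse of 12 months.

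Within TG mice, the comparison of 12 with 2 months spans the onset of disease. Plasma cell genes rose here too, with 13 of 14 higher and a median of 0.60 (0.76 and 0.45 within the replicates, camera adjusted p = 1.8e-12, and adjusted p = 0.21 with an estimated correlation). Among them were Derl3 (506 ± 127 at 12 and 166 ± 67.4 at 2 months) and Creld2 (872 ± 155 and 367 ± 58.4). Dendritic cell genes fell, with 11 of 12 lower and a median of -0.39 (-0.52 and -0.37, adjusted p = 9.81e-07, and adjusted p = 0.118 with an estimated correlation). Among them were Cd209a (61.3 ± 13.0 and 152 ± 14.6) and Ccr7 (399 ± 17.8 and 723 ± 50.4). It was the 1 list that passed fry in this comparison (adjusted p = 0.0177). Targets of p53 rose, with 11 of 12 higher and a median of 0.28 (0.24 and 0.33, adjusted p = 1.06e-05, and adjusted p = 0.118 with an estimated correlation). Among them were Cdkn1a (291 ± 68.4 and 114 ± 25.6) and Zmat3 (235 ± 37.1 and 116 ± 11.6), and the median was 0.46 without the replicate 1 TG mouse of 2 months. No array left out ended these 3 calls.

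Gzma was the 1 gene past the test without a block in any of the 5 comparisons. It fell by 3.12 ± 0.27 on the log2 scale between 2 and 12 months in TG mice (limma adjusted p = 0.0319), from 668 ± 73.7 to 66.0 ± 33.3, with -3.65 within replicate 1 and -2.58 within replicate 2. Leaving out either TG mouse of 12 months kept the Gzma call, and leaving out 1 of the other 6 mice ended it, with an adjusted p of 0.455 without the replicate 1 and 0.28 without the replicate 2 TG mouse of 2 months, and of 0.122 to 0.127 without a WT mouse. In this comparison 528 genes had an unadjusted p under 0.05, 180 higher and 348 lower, where chance gives 559, and 1497 with the replicate block. The calcium channel gene Cacna1s (1.60 ± 0.21), Psrc1 (1.96 ± 0.31) and the enkephalin precursor gene Penk (1.39 ± 0.23) had the smallest p upward and missed the test. With the replicate block 21 genes passed, 11 higher and 10 lower at 12 months, and SEs of these genes are given from the blocked fit. Higher were Derl3 (1.55 ± 0.13), Mid1 (1.89 ± 0.19), Lgals1 (1.01 ± 0.10), Vsig4 (1.63 ± 0.20), Cacna1s (1.60 ± 0.19), Penk (1.39 ± 0.17), the membrane protein gene Ckap4 (1.14 ± 0.14), the serine synthesis gene Phgdh (0.83 ± 0.11), LOC664787 (2.84 ± 0.28) and the immunoglobulin segments Igkv4-72 (1.29 ± 0.15) and Igkv19-93 (1.12 ± 0.14). Lower were Gzma (-3.12 ± 0.23), Ccr9 (-2.11 ± 0.20), Fcer2a (-1.48 ± 0.14) and the chemokine gene Ccl6 (-1.28 ± 0.15). So were Cr2 (-1.25 ± 0.15), Fcrl1 (-1.11 ± 0.13) and Kmo (-1.03 ± 0.13). The leukotriene pathway gene Alox5ap (-1.0 ± 0.13), Ighv14-2 (-0.96 ± 0.13) and Serpinb1a (-0.90 ± 0.10) were lower too. The blocked count was 372 without the replicate 2 and 87 without the replicate 1 TG mouse of 12 months, 0 without any 1 mouse of 2 months and 9 without either WT mouse of 12 months.

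The other 8 of the 11 lists shifted with age in TG mice (7 up, 4 down) each lost the call without 1 of the mice. The 3' to 5' control ratios were lower at 12 months in both replicates (Gapdh 0.843 against 1.07 and 1.21 against 1.48, beta-actin 1.20 against 1.21 and 1.10 against 1.14). G2/M genes had a median of 0.45 (25 of 25 genes higher, 0.99 and -0.08 within the replicates, adjusted p = 2.11e-09, and adjusted p = 0.539 with an estimated correlation). Kif20a stood at 159 ± 17.9 at 12 and 97.7 ± 40.5 at 2 months, and Top2a at 1688 ± 258 and 1125 ± 503. DNA replication genes had a median of 0.25 (29 of 30 genes higher, 0.64 and -0.15, adjusted p = 1.6e-06, and adjusted p = 0.539 with an estimated correlation). Rfc5 stood at 425 ± 21.9 and 284 ± 56.8, and Rfc3 at 146 ± 55.0 and 94.9 ± 31.6. The medians of these 2 lists were 0.01 and -0.02 without the replicate 1 TG mouse of 2 months, both missing the test, and 0.89 and 0.57 without the replicate 2 mouse of that age, and without the replicate 1 TG mouse of 12 months DNA replication had 0.15 and missed the test. The MYC growth list rose with a median of 0.25 (19 of 22 genes higher, 0.31 and 0.19, adjusted p = 1.28e-05, and adjusted p = 0.241 with an estimated correlation). Eif4e stood at 1013 ± 134 and 669 ± 7.97, and Polr1b at 243 ± 9.02 and 162 ± 27.4. The growth list missed the test without the replicate 1 TG mouse of 2 months (0.13). The lymphoid progenitor list fell with a median of -0.28 (7 of 10 genes lower, -0.50 and -0.15, adjusted p = 0.00404, and adjusted p = 0.241 with an estimated correlation). Ccr9 stood at 32.7 ± 2.38 and 199 ± 66.5, and Flt3 at 178 ± 1.20 and 270 ± 32.8. B cell genes fell with a median of -0.26 (15 of 19 genes lower, -0.61 and -0.04, adjusted p = 0.00686, and adjusted p = 0.539 with an estimated correlation). Cr2 stood at 495 ± 98.5 and 1183 ± 38.1, and Fcer2a at 382 ± 119 and 1074 ± 163. Both calls were lost without the replicate 1 TG mouse of 12 months (-0.24 and -0.02), and the B cell median was -0.19 and missed the test without the replicate 1 TG mouse of 2 months and was -0.61 without the replicate 2 TG mouse of 12 months.

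Macrophage genes had a median of -0.24 with age in TG mice (17 of 22 genes lower, -0.49 within replicate 1 and 0.06 within replicate 2, adjusted p = 0.0205, and adjusted p = 0.732 with an estimated correlation). Timd4 stood at 338 ± 78.6 at 12 and 676 ± 181 at 2 months, and Marco at 307 ± 341 and 820 ± 60.7. The macrophage list stood at 0.02, with the test missed, without the replicate 1 TG mouse and at -0.45 without the replicate 2 TG mouse of 12 months, and at -0.16, with the test missed, without the replicate 2 TG mouse of 2 months. Glycolysis genes had 0.21 (12 of 14 genes higher, 0.45 and 0.01, adjusted p = 0.00354, and adjusted p = 0.539 with an estimated correlation). Tpi1 stood at 926 ± 236 and 632 ± 63.2, and Pfkp at 675 ± 230 and 452 ± 30.6. Glycolysis genes stood at 0.04 without the replicate 1 TG mouse of 12 months and at 0.27 without the replicate 2 TG mouse of 2 months, both missing the test, and at 0.48 without the replicate 2 TG mouse of 12 months. The regulatory and exhausted T cell list had 0.31 (8 of 11 genes higher, 0.73 and -0.06, adjusted p = 0.0341, and adjusted p = 0.539 with an estimated correlation), a call that the replicate block ended (adjusted p = 0.0996). Ctla4 stood at 189 ± 132 and 71.8 ± 4.35, and Cxcr5, which went the other way, at 602 ± 53.2 and 836 ± 123. The regulatory T cell list stood at -0.10, with the test missed, without the replicate 1 TG mouse of 12 months, at 0.78 without the replicate 2 mouse, and at 0.36 and 0.24, with the test missed, without the replicate 1 and replicate 2 TG mouse of 2 months. The unmoderated model ended the calls of macrophages (adjusted p = 0.0994), B cells (0.0558) and regulatory T cells (0.134). The last was also lost with no filter on dim probe sets (0.115), with the stricter filter (median 0.13, adjusted p = 0.569) and with the mean of a gene's probe sets (0.0592). The number of shifted lists was 17 without the replicate 2 TG mouse of 12 months.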

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

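The 3 tests of the pattern in growth genes, the test of the transgene as the source of the pancreatic pattern, and both tests of the 2 TG mice were chosen after the result was seen. The test by further pancreatic genes was set before the values of those genes were seen. By a test of the difference of the 2 effects, 9 gene lists differed between 12 and 2 months, of which 7 lost the call without 1 array. The median log2 differences were 0.35 for MYC growth genes, 0.24 for DNA replication, 0.31 for G2/M and mitosis, 0.12 for p53 targets, 0.25 for glycolysis and hypoxia and 0.34 for T cells (-0.02 and -0.17 without the replicate 1 TG mouse of 12 months), 2.04 for exocrine pancreas (0.05 without the replicate 1 WT mouse of 2 months), -0.50 for macrophages and -0.47 for dendritic cells. None of the 9 passed with an estimated correlation. Probe sets without a single gene symbol, which no comparison of genes used, also passed the test: 1 between 12 and 2 months in TG mice, and with the replicate block 14 between TG and WT mice at 12 months and 9 between the ages in TG mice.

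Growth, DNA replication and mitosis genes were higher in the TG mice of 12 months by camera at a preset correlation, and none of the 3 lists passed with an estimated one (adjusted p = 0.257, 0.449 and 0.449). A replicate difference that is alike in all groups cancels from this comparison, since each group has 1 mouse of each number, so it cannot give this pattern. The 3 medians were positive within both replicate numbers, the smallest being 0.26. The scaling of each array by 1 factor is argued against, since the smallest of the 3 medians under quantile, loess or median scaling was 0.43. A larger share of erythroid or myeloid precursors, which divide, could not be told apart from more division in other cells. The erythroid median was -0.19 within replicate 1, where the mitosis median was 0.52, but 0.34 within replicate 2. The neutrophil list was split the same way, lower within replicate 1 and higher within replicate 2, and 1 pair of mice decides neither way. RNA quality was not tested and stays open: the 3' to 5' ratios of both control genes were lower in TG than in WT mice within both replicates (Gapdh 0.843 against 1.25 and 1.21 against 1.73). The transgene itself and the tumour cells it leads to stay open and were not tested apart.

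Exocrine pancreas genes were lower in TG than in WT mice at 2 months. An effect of the transgene in both pairs of mice is argued against, since the list's median was 0.11 within replicate 2. Without the replicate 1 WT mouse the median was 0.35. Pancreatic tissue in the spleen sample of the replicate 1 WT mouse is a candidate explanation: of 22 probe sets of 13 further pancreatic genes outside the tested list, 17 (77.3%) had their highest signal on that array, where chance gives 12.5%, with a median of 188 against 19.5 on the other 7 arrays. Of the 15 genes of the tested list, 8 passed the filter on dim probe sets, and no other list holds any of them. The most abundant were Cela1, at 1979 ± 2323 in WT and 378 ± 7.61 in TG mice of 2 months, and Cela2a, at 1812 ± 2503 in WT mice. The labels name no sorting of cells that would remove such tissue.

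The 2 TG mice of 12 months differed from each other in T cell and B cell genes. Batch is argued against, since the T cell list differed between replicate 1 and replicate 2 by 0.78 in these mice and by -0.13 to 0.17 in the other 3 groups. A scaling error of 1 array is argued against, since the B cell list differed by -0.62, opposite to the T cell list. The NK and cytotoxic list differed by 0.73, the regulatory and exhausted T cell list by 0.73 and the macrophage list by -0.64, the last against -0.35 to 0.08 in the other 3 groups. No biological explanation was tested, since both mice belong to 1 group of the design.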

How the results depend on the processing

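The replicate block combined with every probe set, and with each array left out, was added after the data were seen. Of 49 shifts of lists, 46 kept their direction and side of the threshold with the replicate block and 3 lost the call (T cells at 2 months, interferon at 12 months, regulatory T cells with age in TG mice). Camera with an estimated correlation kept 0 of the 49 calls, and fry kept 2. Under the remaining alternatives that kept all arrays, 556 of 576 values did so, 20 lost the call and 0 reversed. With 1 array left out, 325 of 392 did so, 48 lost the call and 19 reversed. Of the 19, 4 passed the test in the opposite direction. Part of the 392 values leave out an array outside a comparison of 2 groups, where the median of a list cannot move, so the share kept is flattering. All losses and reversals came from arrays of the comparison. The fits with 1 array left out have no block, so leaving out an array unbalances the replicate numbers, and part of such changes can be the replicate difference. No scaling moved the median of all genes by over 0.1. Both planned results on Hmga1 were not run, as no probe set carried that symbol alone. The block added 2 list calls (MYC growth at 2 months, adjusted p = 0.0411, and megakaryocytes and platelets for the difference, 0.0422). Between 25% and 28.7% of the probe sets of an array lay under a signal of 16, and weak genes were not tested. The cause of the changes below was not tested, except that fewer arrays widen the error.

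No list passed with an estimated correlation in any comparison (0 in each of 5). Fry called 0 at 2 months, 1 at 12 months, 0 for the difference, 0 with age in WT and 1 with age in TG mice. With the replicate block 5 genes passed at 12 months (55 probe sets when every one is counted) and 21 with age in TG mice (35 probe sets). The 1 gene with age in TG mice, Gzma, became 0 with a pseudocount of 1 (adjusted p = 0.0533), with the unmoderated model or with the arrays of the comparison alone, and 2 with every probe set counted. The adjusted p of Gzma over all alternatives ran from 0.00603 to 0.651. The unmoderated model called 1 gene for the difference, Zfp821, named after its value was seen. The correlation of the effects at the 2 ages was 0.114 with no filter.

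With 1 array left out, the genes past the test numbered 0 to 2 at 2 months, 0 to 7 at 12 months (0 to 731 with the block), 0 for the difference, 0 to 4 with age in WT and 0 to 4 with age in TG mice (0 to 372 with the block). Lists numbered 3 to 10, 5 to 15, 4 to 16, 5 to 12 and 8 to 17 in the same order, and the correlation ran from 0.0696 to 0.218.

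Values that reversed did so without 1 array, and each is given with the lowest and highest of its values without 1 array. At 2 months neutrophils ran from -0.46 (without TG_2m replicate 2, and -0.18 without WT_2m replicate 1) to 1.19. Exocrine pancreas ran from -4.21 to 0.35 (without WT_2m replicate 1) and Cela1 from -3.21 to 0.16 (same array). Without TG_2m replicate 2 the lowest were -0.15 for G2/M (highest 0.67), -0.10 for DNA replication (0.48), -0.11 for Tpx2 (0.98), -0.13 for Nusap1 (0.85) and -0.079 for Ccne1 (0.95). At 12 months, without TG_12m replicate 1, T cells had -0.012 (highest 0.88) and interferon -0.074 (0.33). For the difference of the effects, without TG_12m replicate 1, T cells had -0.17 (0.65) and glycolysis -0.018 (0.49), and without TG_2m replicate 1, G2/M had -0.11 (0.77) and DNA replication -0.083 (0.54). With age in WT mice, neutrophils ran from -0.84 to 0.26 (without WT_2m replicate 2, and 0.04 without WT_12m replicate 2) and stroma from -0.24 to 0.014 (without WT_2m replicate 2). Without WT_2m replicate 1, erythroid genes had -0.10 (highest 0.62), pancreas 0.00042 (lowest -4.43) and Rrp9 0.025 (lowest -0.97), and without WT_12m replicate 1, Rhag had -0.0099 (highest 0.87). With age in TG mice, without TG_12m replicate 1, regulatory T cells had -0.10 (highest 0.78) and macrophages 0.022 (lowest -0.45), and without TG_2m replicate 1, DNA replication had -0.017 (highest 0.57).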

Other observations

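Beside the growth genes, 4 further lists placed both TG mice of 12 months outside the range of the other 6 mice. Relative to a gene's mean over all arrays, p53 targets stood at 0.28 and 0.31 in these 2 mice and at no more than 0.05 in the others, glycolysis and hypoxia at 0.39 and 0.08 against 0.01, dendritic cells at -0.37 and -0.37 against at least 0.01, and lymphoid progenitors at -0.29 and -0.20 against at least 0.02. The other 21 lists did not.

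The replicate 1 TG mouse of 12 months held the highest signal among all 8 mice for several genes of cytotoxic lymphocytes, which were picked out after their values were seen. Its Ccl5 signal was 5303, against 3455 in the other TG mouse of that age and 1215 and 2176 in the WT mice. Klrc1 stood at 788, 150, 184 and 102 in the same order, Eomes at 594, 284, 156 and 214, and Cd8a at 1261, 440, 257 and 482. Gzmb, which encodes granzyme B, stood at 115, 53, 52.5 and 61.0 but was highest, at 127, in the replicate 1 TG mouse of 2 months. Gzma went the other way and was lowest in the replicate 1 TG mouse of 12 months, at 42.5, 89.6, 338 and 337.

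Gzmm was higher in both TG mice than in both WT mice at either age, while the NK and cytotoxic list as a whole had a median of 0.06 at 2 months (camera adjusted p = 0.842) and of 0.28 at 12 months (12 of 17 genes higher, 0.66 and -0.03 within the replicates, adjusted p = 0.0762). No explanation was tested.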
